A study of Mus musculus with 12 samples.

How the data were processed

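The samples were single-cell RNA libraries, 1 per animal, of cells sorted on green fluorescence from the cortex of Aldh1l1 reporter mice, 3 animals in each of 4 groups (female or male, LPS or saline), as given by the labels. The deposited files hold whole-number UMI counts per gene and cell barcode, which the authors made with Cell Ranger 3.0.2 on mm10, per the submitters' processing notes and the file headers. The annotation and any filter beyond cell calling are not given in the sources used here; the lowest total of a deposited barcode was 500 UMIs. No normalisation was applied to the counts before deposit, as far as their values show. The files list 31053 genes. Gene positions were taken from GENCODE M21 on GRCm38, matched by gene identifier; of 137 genes named by rule 136 had a position.

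Barcodes with at least 500 detected genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were retained (83561 of 116707). Doublets were scored in each library against simulated doublets (2 per cell, 1500 variable genes, 30 components), and the top share was called at a rate of 0.8% per 1000 barcodes, 7834 cells or 9.38% of those passing (3.07% in saline male 2 to 15.3% in LPS female 1). All cells passing the filter, called doublets included, were scaled to 10000 UMIs, log transformed and clustered with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, which gave 23 clusters. Called doublets were removed after the clusters had been given a class. A cluster was given the class whose markers, fixed before the data were examined, had the highest median fold over the other cells (at least 5, with at least 3 markers detected in at least 10% of its cells, folds with an offset of 10 CPM). Where no class met this, the cluster was called astrocyte-like if at least 3 astrocyte markers were detected in at least 10% of its cells. All 15 astrocyte-like clusters came by this second part, since most cells are astrocytes and the median fold of the astrocyte markers was at most 1.2 after rounding. Astrocyte-like thus means that markers were detected and no other class led, and free RNA can add to such detection. Cluster 8 is astrocyte-like in this way, and its class is in doubt: when set against all other cells, its 10 leading genes hold 1 marker of another class and no astrocyte marker; set against cells of other classes they hold 1 astrocyte marker. Clusters 10, 11 and 15 have low depth. The counts were therefore also given without cluster 8 and without clusters 10, 11 and 15. UMIs of droplets also hold free RNA of other cells, and no correction for it was made; levels in a class are therefore set beside those in astrocyte-like cells.

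Raw counts were summed per animal over astrocyte-like cells and tested with edgeR 4.0.16 in R 4.3.3 (trimmed mean of M-values normalization, filterByExpr, glmQLFit and glmQLFTest, 4 group means in 1 fit of 12 animals). Tested were 6 contrasts: LPS against saline over both sexes, in females and in males, the male minus the female LPS effect, and male against female in saline and in LPS. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes come from the fitted model, and their SE from the fold change and its F statistic. CPM were computed with the normalised library sizes, and mean ± SD were taken over animals; principal components used log2 CPM with a prior count of 2. For a gene at 0 over a whole treatment the fold is a lower bound from a floor of 3 counts over that group; with 1 to 3 UMIs the ratio of CPM is given with a 95% counting interval. Intervals and floors cover counting error alone. Replicates are separate animals per the labels, and 12 pairs of libraries within groups differed by 4.11 to 31.7 in chi-square per gene, so none was counted as a copy of another.

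Lists of genes were fixed before the data were examined: type I interferon response, interferon-inducible GTPases, MHC class I antigen presentation, NF-kB targets with cytokines and chemokines, acute phase and STAT3 targets, pan-reactive, A1 and A2 astrocyte genes, complement, astrocyte transporters and channels, astrocyte matrix and synapse regulators, cholesterol synthesis, glucocorticoid targets, circadian clock, ER stress, dissociation and immediate early genes, oxidative phosphorylation and ribosomal proteins. The lists were written from general knowledge and not copied from published tables, so the pan-reactive, A1 and A2 lists can differ from those of earlier work. Some genes stand in more than 1 list, such as Lcn2, Serpina3n, Fkbp5, Serping1 and Iigp1. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside camera with an estimated correlation and fry; p was adjusted over the 18 lists of a contrast. Of the 18 lists fry called 15 in the main contrast. Sums over neuron-like and endothelial-like cells were tested with edgeR with treatment and sex as terms, in animals with at least 20 cells of the class and for classes with at least 3 such animals per treatment.

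Shares of classes and of cells with interferon-list transcripts were compared by two-sided exact permutation tests over animals. For the latter each cell was thinned to 1500 UMIs, shallower cells were left out, and cells with at least 3 UMIs of the 44 genes of both interferon lists were counted; this class is a range of a count, not a cell type. Subclusters of astrocyte-like cells came from the 2000 most variable genes of saline cells less those called with an absolute log2 fold change of at least 0.5, which left 1564, at Leiden resolution 0.5. The sum over a subcluster was tested against that over the animal's other astrocyte-like cells, with animal as a block, and adjusted over all genes and subclusters.

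The genes named were fixed by a rule written before the data were examined. For LPS against saline these are the 14 largest rises and 12 largest falls among called genes with at least 20 CPM in the higher treatment, no overlap between the animals of the treatments, and no place among markers of another class (908 and 576 candidates), and up to 4 called members of each list with the largest absolute change. For sex contrasts they are the 8 smallest adjusted p, for other classes 8 rises and 4 falls, for each subcluster 4 genes, and always Aldh1l1, Gfap, Xist and 4 Y-linked genes. List members named beyond these, and Calr, Per1 and C4b where they fall outside the rule, were chosen after their values were seen, as were the list tests in neuron-like and endothelial-like cells. Results for some genes that the rule names are not reported here.

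The tests were tested on simulated data with the depths of these libraries and, before changes were added, the same mean of a gene in all animals. At each of 2 sizes 100 genes were changed, drawn from those above the lowest quartile of level. Far more genes were called in the data, so recovery there can differ. For LPS against saline (14001 genes), 93% of genes changed by 0.5 on the log2 scale were recovered and 100% of those changed by 1; in females (14001 genes) 57% and 100%, for the interaction (14000 genes) 21% and 84%, and for male against female in LPS (14000 genes) 62% and 100%. The recovered shares were 39% and 96% in neuron-like sums (9197 genes), 24% and 77% in endothelial-like sums (4128 genes) and 54% and 90% in subcluster 5 (12255 genes). Unchanged genes made up 11 of 204 calls for LPS against saline, 6 of 163 in females and 9 of 114 for the interaction. They made up 8 of 170 for male against female in LPS and 9 of 144 in neuron-like sums. In endothelial-like sums they made up 4 of 105, and in subcluster 5 10 of 154.

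Alternatives were DESeq2 1.42.0, median-of-ratios size factors, no low-count filter, a stricter cell filter (at least 1000 genes and at most 5% mitochondrial UMIs), doublets retained, libraries thinned to the smallest total, classes per cell, the replicate number as a term, other UMI limits and depths, Leiden resolutions of 0.3 and 1, at least 50 cells per animal, and each animal left out in turn. The runs without cluster 8 and without clusters 10, 11 and 15 were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 was used for the cells and plots. Day of collection, litter and sequencing batch are not in the labels, and no correction for them was made.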

Results

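The series measured RNA in single cells sorted from the cortex of mice aged 30 to 35 days that carry green fluorescent protein under the promoter of Aldh1l1, a folate enzyme used as an astrocyte marker. Each animal had received LPS, a component of bacterial outer membranes that triggers innate immune signaling, at 5 mg per kg, or saline, and cells were collected 24 h later. Sex and treatment make 4 groups of 3 animals, 12 in all, with 1 droplet library per animal. The libraries held 116707 barcodes, 3861 to 19138 per animal, with 13522232 to 53508694 UMIs each. After filtering and removal of 7834 called doublets, 75727 cells remained, of which 71534 (94.5%) fell in astrocyte-like clusters. The sums over astrocyte-like cells, on which the gene tests rest, held 9626707 to 34909975 UMIs from 2221 to 11772 cells per animal, with median depths of 2795 to 4344 UMIs per cell. Values below are CPM of these sums, UMI counts relative to the total of the sum, as mean ± SD, with n = 3 animals per group or n = 6 per treatment, and log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p.

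Sex-linked genes matched the sex in the labels of all 12 animals. Xist, the noncoding RNA that silences the second X chromosome, stood at 1612 CPM or more in each female and at 0.549 CPM or less in each male. Ddx3y, a Y-linked RNA helicase gene, stood at 73.2 CPM or more in each male and at 0.0438 CPM or less in each female. Astrocyte-like cells of saline animals lay mostly in clusters 3, 5 and 6 (88.4% of them), and those of LPS animals mostly in clusters 1, 2, 4 and 7 (74.3%), so the values below compare different clusters of 1 class. The clusters were built without leaving out genes that LPS changed, so this division can reflect the same differences in expression that are tested below.

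The first comparison asks what systemic LPS changed in sorted cortical astrocytes after 24 h. The largest rises included genes of secreted proteins. Lcn2, which encodes an iron-siderophore binding protein, went from 0.104 ± 0.102 CPM in saline to 764 ± 369 CPM after LPS (log2 fold change 12.91 ± 0.60, n = 6 per treatment, adjusted p = 1.81e-10). Serpina3n, a secreted protease inhibitor gene, went from 6.97 ± 1.71 to 608 ± 220 CPM (6.42 ± 0.26), and Timp1, an inhibitor of matrix metalloproteinases, from 0.545 ± 0.315 to 114 ± 69.4 CPM (7.52 ± 0.38). Gfap, the intermediate filament gene used as a mark of reactive astrocytes, rose from 250 ± 54.8 to 1235 ± 226 CPM (2.31 ± 0.11). The largest falls included Tnc, an extracellular matrix glycoprotein gene, from 37.4 ± 8.70 to 8.53 ± 3.99 CPM (-2.25 ± 0.10), and Vegfa, the vascular endothelial growth factor, from 274 ± 54.0 to 94.8 ± 14.2 CPM (-1.53 ± 0.10).

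Among the other genes with the largest rises were Lrg1, a secreted leucine-rich glycoprotein gene (8.89 ± 0.70), and Fcgr2b, an inhibitory receptor for immunoglobulin G (8.57 ± 0.53). Gpx3, a secreted glutathione peroxidase gene, rose by 5.94 ± 0.16 and Serping1, the inhibitor of complement C1, by 5.82 ± 0.25. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 5.72 ± 0.15, Fbln5, an extracellular matrix protein gene, by 5.51 ± 0.15, and Srgn, a proteoglycan core protein gene, by 5.62 ± 0.26. Map3k6 rose by 5.88 ± 0.25, Glycam1 by 5.30 ± 0.23, and the interferon-inducible GTPase genes Gm4951 and Iigp1, close copies whose reads may be split between them, by 5.87 ± 0.49 and 5.67 ± 0.55. Beside Tnc and Vegfa, the falls included Apln, a peptide ligand (-1.86 ± 0.11), Ptgs1, the constitutive cyclooxygenase (-1.77 ± 0.09), Epha4, an ephrin receptor (-1.48 ± 0.09), and Alpl, an alkaline phosphatase (-1.43 ± 0.07). Hes1, a transcriptional repressor downstream of Notch, fell from 198 ± 22.2 to 75.4 ± 21.6 CPM (-1.41 ± 0.12), and Tle2, a corepressor, changed by -1.40 ± 0.09. Fam184b (-1.54 ± 0.10), Col11a2 (-1.52 ± 0.09) and the noncoding transcripts AC160336.1 (-2.07 ± 0.28), which overlaps Gm5624, and CT025619.1 (-1.61 ± 0.11) completed the 12 largest falls. Aldh1l1, the source of the sort promoter, rose by 0.49 ± 0.07. Slc10a6, a sulfated steroid transporter gene without a UMI in saline astrocyte-like cells, was at least 240-fold higher after LPS, from a floor of 3 counts over the saline group.

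In the mouse assembly GRCm38, with GENCODE M21 coordinates counted from 1, Lcn2 (ENSMUSG00000026822) lies on chromosome 2 at 32384633 to 32388252, Serpina3n (ENSMUSG00000021091) on chromosome 12 at 104406729 to 104414329, and Timp1 (ENSMUSG00000001131) on chromosome X at 20870166 to 20874735. Gfap (ENSMUSG00000020932) lies on chromosome 11 at 102887336 to 102900912, Lrg1 (ENSMUSG00000037095) on chromosome 17 at 56119678 to 56122001, Tnc (ENSMUSG00000028364) on chromosome 4 at 63959785 to 64047015, and Vegfa (ENSMUSG00000023951) on chromosome 17 at 46016993 to 46032369. Far1 (ENSMUSG00000030759), described with the sex comparison, lies on chromosome 7 at 113513834 to 113571511, and Mrpl41 (ENSMUSG00000036850) on chromosome 2 at 24974117 to 24975098. All 9 are protein-coding genes, and their values are sums over the whole gene. Timp1 overlaps Syn1 and Far1 overlaps Far1os on the other strand; the sources used here do not state whether counting used the strand, so their levels are uncertain.

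**Figure D1:**
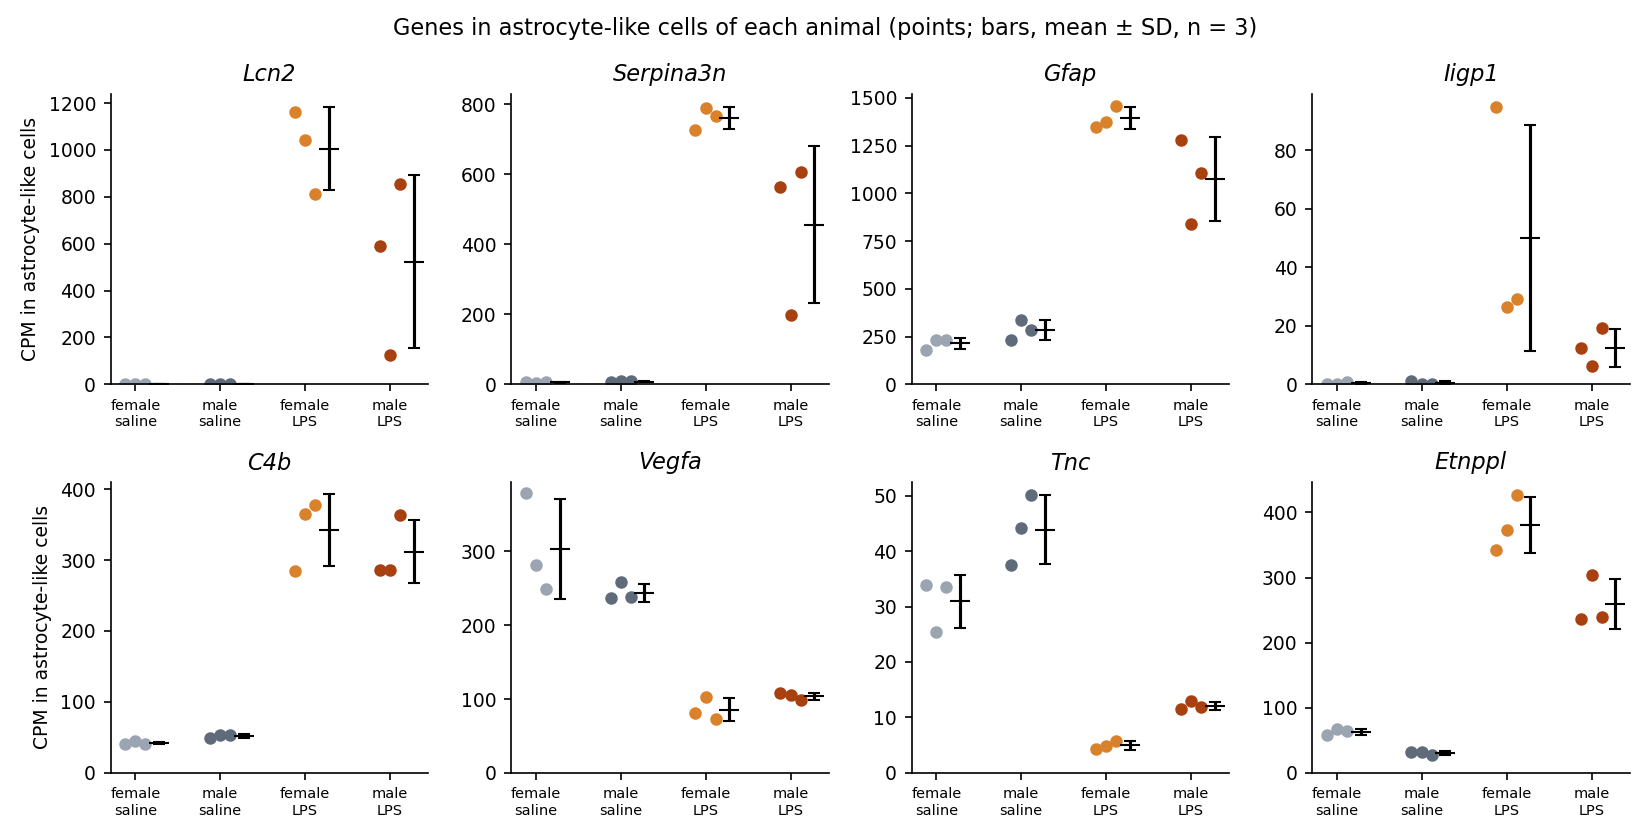
CPM of 8 genes in astrocyte-like sums, 1 point per animal, with the mean and SD (n = 3) of each sex and treatment group. Lcn2, Serpina3n, Gfap, Iigp1, C4b and Etnppl stood higher and Vegfa and Tnc lower in LPS animals; Lcn2 in LPS males had a mean of 524 and an SD of 368 CPM.

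Gene lists fixed before the data were examined described the response by function; "called" means adjusted p under 0.05 over all 14178 genes tested, and counts of astrocyte-like sums adjusted over the list alone were the same except where given. All 28 type I interferon response genes tested rose (median log2 fold change 3.05), among them Oasl2 (4.51 ± 0.25), Usp18 (4.14 ± 0.24) and Oas1a (4.09 ± 0.56), and Zbp1, with 1 UMI in saline, stood 243-fold higher (95% counting interval 43.4 to 9640). All 14 interferon-inducible GTPase genes rose (median 3.98); Gbp4 and Gbp9, which overlap each other and had 1 UMI in saline, stood 99.9-fold (17.7 to 3970) and 93.9-fold (16.6 to 3730) higher. All 16 genes of MHC class I antigen presentation rose (median 2.27), led by the immunoproteasome subunit Psmb8 (5.24 ± 0.34), the transactivator Nlrc5 (4.29 ± 0.28), H2-T23 (4.25 ± 0.27) and H2-Q4 (4.20 ± 0.40); the H2-Q genes are near-identical copies, so H2-Q4 is uncertain. Of 20 NF-kB targets, cytokines and chemokines 16 rose and 3 fell, with a median of 1.06. The chemokine genes Cxcl1 (5.50 ± 0.39) and Ccl2 (4.77 ± 0.56) rose, Cxcl9, with 1 UMI in saline, stood 115-fold higher (20.4 to 4560), and Ccl5, with none, at least 53.4-fold higher. These levels after LPS were low, at 2.62 ± 0.679 CPM for Cxcl1, 3.37 ± 2.93 for Ccl2, 1.66 ± 1.09 for Ccl5 and 1.10 ± 1.17 for Cxcl9. Markers of other classes rose in the same sums: the microglia genes C1qa from 1.10 ± 0.641 to 6.83 ± 3.56 CPM and Ctss from 0.888 ± 0.590 to 3.38 ± 1.59 CPM, and the endothelial gene Cldn5 from 2.13 ± 0.684 to 3.50 ± 2.01 CPM. The microglia-like share of cells also rose (0.312% to 0.947%, described below), and endothelial-like cells, near 1% of all, held Cxcl1 at 314 CPM after LPS. Genes at a few CPM, C3 and Cd14 (3.61 ± 1.67 CPM after LPS) among them, stand beside these values, and no correction for RNA of other cells was made. Tnfaip3, an inhibitor of NF-kB signaling, fell by 0.85, Lif by 0.43 and Vcam1 by 0.33 on the log2 scale, and Nfkb2 was not called. Of 17 acute phase and STAT3 targets 15 rose and Il4ra fell by 0.73 (median of the list 3.02). Steap4, a metalloreductase gene with 1 UMI in saline, stood 777-fold higher (139 to 30700), and Serpina3m, which had none and overlaps its paralog Serpina3k, at least 50.1-fold higher. All 9 complement genes rose (median 2.81), including C3 from 0.0624 ± 0.0523 to 9.35 ± 2.29 CPM (6.91 ± 0.31), C1ra (6.79 ± 0.54) and C1s1 (4.26 ± 0.35).

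Lists of reactive astrocyte genes, written from general knowledge of earlier work in other animals and not copied from its tables, rose as well. Of 13 pan-reactive genes 12 rose (median 3.93) and Cd44 was not called. All 11 A1 genes, first described as induced by LPS, rose (median 5.24), led by Serping1, Fkbp5, Iigp1 and Srgn. Of 10 A2 genes, first described as induced by ischemia, 8 rose (median 1.70), including Cd14 (3.60 ± 0.30), Cd109 (3.22 ± 0.16) and Tgm1, which had 1 UMI in saline and stood 80.1-fold higher (14.1 to 3190); B3gnt5 and Emp1 were not called. Of 15 glucocorticoid targets 13 rose (median 1.04), led by Fkbp5, the lipid droplet gene Plin4 (4.61 ± 0.24), the cell cycle inhibitor Cdkn1a (3.87 ± 0.18) and Sult1a1 (2.24 ± 0.12), and Pdk4 and Errfi1 were not called.

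Each of the remaining lists held called genes in both directions. Of 24 cholesterol synthesis genes 14 fell and 1 rose (median -0.26). The falls included Mvd (-1.02 ± 0.09) and Dhcr7 (-0.92 ± 0.07), and Ebp rose from 20.8 ± 2.94 to 41.6 ± 6.94 CPM. Of 20 transporters and channels 7 rose and 5 fell. The gap junction gene Gjb6 went from 613 ± 141 to 1290 ± 321 CPM (1.07 ± 0.09). The amino acid transporters Slc38a3 (-0.88 ± 0.11) and Slc7a10 (-0.56 ± 0.05) and the glutamate receptor Grm3 (-0.66 ± 0.08) fell. Slc7a10 overlaps Lrp3 on the other strand. Of 17 matrix and synapse regulators 3 rose and 8 fell, with Sparc at 1.77 ± 0.09, Gpc4 at 0.89 ± 0.08 and Ncan at -1.16 ± 0.07 beside Tnc. Of 16 clock genes 7 rose, including Per1 (0.95 ± 0.08), Per2 (0.84 ± 0.09) and Ciart (0.83 ± 0.09), and Arntl fell (-0.75 ± 0.07). Of 15 ER stress genes 3 rose and 8 fell (median -0.17, mean 0.06); Chac1 rose (2.11 ± 0.35), Herpud1 rose (0.39 ± 0.07), and the chaperone Calr (-0.59 ± 0.07) and Xbp1 (-0.50 ± 0.07) fell. Of 17 immediate early and dissociation genes 6 rose, led by Ier3 (2.54 ± 0.16), Junb (1.47 ± 0.15), which overlaps Prdx2, Atf3 (1.16 ± 0.33) and Zfp36 (0.96 ± 0.11), and Jun, Dusp1 and Dnajb1 fell. Over the alternatives the adjusted p of Atf3 ranged from 0.00222 to 0.109, that of Cox7a1 from 6.02e-05 to 0.0529, both highest with the stricter cell filter, and that of Rpl3l from 0.00122 to 0.136, highest with libraries thinned. Of 86 oxidative phosphorylation genes 27 rose and 5 fell (25 and 3 adjusted over the list alone), with Ndufc2 at 0.76 ± 0.08, Cox4i2 at 0.55 ± 0.10, Cox7a1 at -0.48 ± 0.12 and Cox8b at -1.70 ± 0.25. Of 78 ribosomal protein genes 48 rose and 1 fell (54 and 1 adjusted over the list alone). Rpl3l changed by 0.77 ± 0.19, Rps4x by 0.76 ± 0.07, and Rps14 and Rps6 by 0.44 ± 0.07 each; ribosomal pseudogenes can share these reads.

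**Figure D2:**
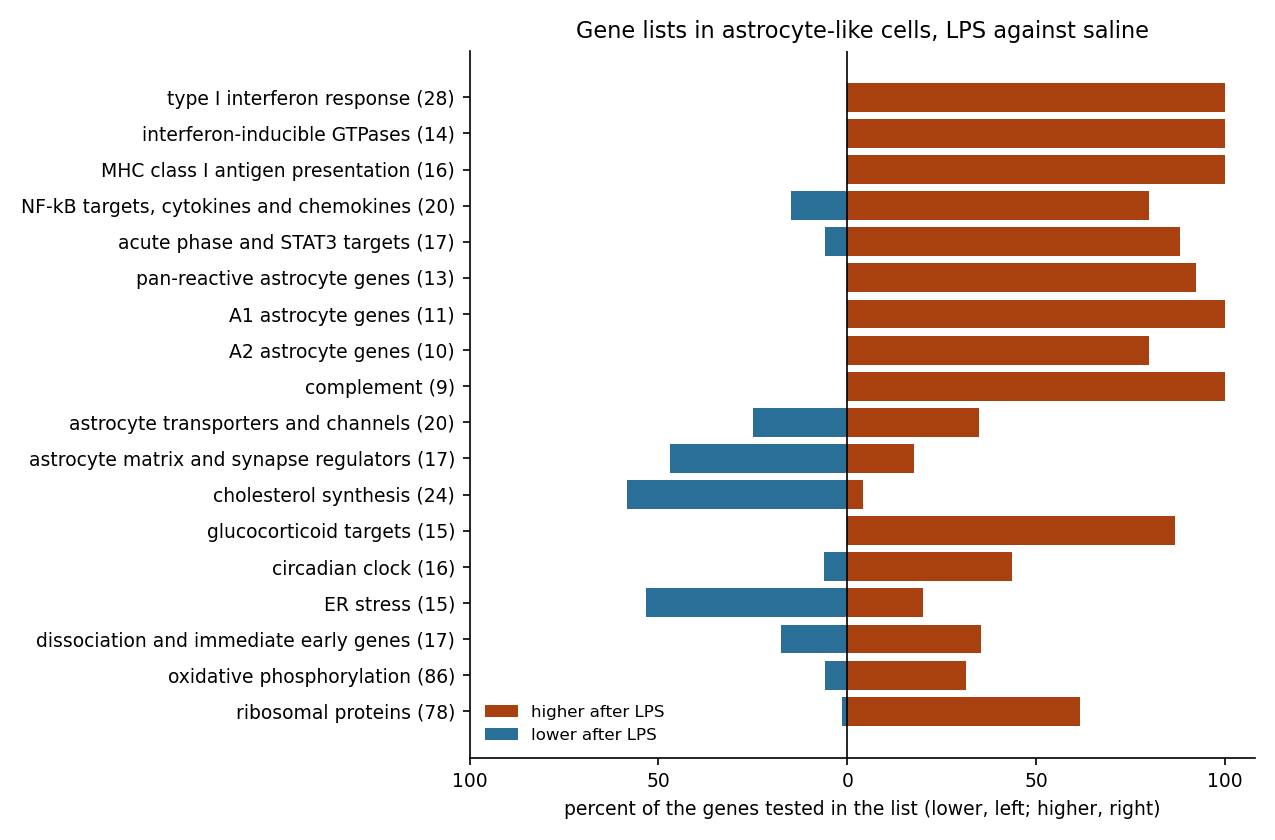
Percent of each list's tested genes called higher (right) and lower (left) after LPS in astrocyte-like sums over both sexes, with the number tested in brackets. The interferon, GTPase, MHC class I, A1 and complement lists were called higher in full; cholesterol synthesis had 14 of 24 called lower.

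In all, 6638 of 14178 genes were called, 3243 higher and 3395 lower, and 1012 of them changed by at least 2-fold. The set test camera with a preset correlation of 0.01 called 13 of the 18 lists, 12 up and cholesterol synthesis down; transporters (adjusted p = 0.889), matrix and synapse regulators (0.0885), clock (0.0866), ER stress (0.253) and immediate early genes (0.188) were not called. With an estimated correlation 10 of the 13 calls held, and those lost were cholesterol synthesis (adjusted p = 0.331 with an estimated correlation), oxidative phosphorylation (adjusted p = 0.742) and ribosomal proteins (adjusted p = 0.531). By camera, oxidative phosphorylation was also lost without saline female 1 (adjusted p = 0.0795), saline male 1 (0.174), LPS female 1 (0.127), LPS female 2 (0.0797), LPS male 1 (0.0779) or LPS male 2 (0.0875), and with the replicate block (0.0624), with 0.000736 to 0.742 over all runs of camera. The clock was gained by camera without saline male 3 (0.041) or LPS male 3 (0.0483), with up to 0.441 over its runs. The set test fry, which tests a list against no change, did not call oxidative phosphorylation (0.112). Of the lists that camera did not call, fry called the clock up (0.00153), matrix and synapse regulators down (0.000844) and immediate early genes up (0.0399). At the preset correlation camera also called 13 or more lists in 38 of 100 splits of the animals, the real one included. LPS libraries held 7763 to 19138 barcodes and saline libraries 3861 to 8946, and Aldh1l1, whose promoter drives the reporter used for the sort, itself rose.

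Lcn2, Serpina3n and Gfap rose in each sex, and most of the genes that changed at least 2-fold over both sexes moved further in females. Lcn2 reached 1005 ± 177 CPM in LPS females and 524 ± 368 CPM in LPS males, Serpina3n 760 ± 31 and 456 ± 224 CPM, and Gfap 1394 ± 57.9 and 1076 ± 221 CPM (n = 3 each). Among the LPS males, male 2 stood at 126 CPM for Lcn2, against 592 and 853, and at 198 CPM for Serpina3n, against 565 and 605. The difference in the Lcn2 change between the sexes was not called (adjusted p = 0.775). LPS males and LPS females lay mostly in different clusters. Clusters 1 and 4 held 20.4% ± 12.2 of the astrocyte-like cells of LPS females and 70.6% ± 5.31 of those of LPS males, and clusters 2 and 7 held 53.5% ± 8.71 and 4.04% ± 2.37 (n = 3 each). The comparisons of the sexes after LPS, and of their LPS effects, thus compare different clusters. Since genes that differ were not left out when the clusters were built, this division is not a result apart from the gene tests. It does not show that different populations of astrocytes are compared. In females 3091 genes were called higher and 3055 lower, and in males 1557 and 1071. Of the 1012 genes that changed at least 2-fold over both sexes, 1009 moved the same way in both and 833 moved further in females, and the slope of the male on the female log2 fold change through 0 was 0.699. Across these genes, which are not independent replicates, Pearson's r was 0.906 and Spearman's rho 0.83. With every library thinned to the smallest total, the male count was 1560, with 1067 higher and 493 lower.

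All 28 type I interferon genes rose in females, and in males 27 rose (28 adjusted over the list alone). The GTPases rose in 14 of 14 and 11 of 14 genes (12 adjusted over the list alone), and MHC class I in 16 and 15 of 16 (16 and 16). The counts were 11 and 11 of 11 for A1, 9 and 8 of 9 (9 and 9) for complement, and 13 and 11 of 15 for glucocorticoid targets. Of 17 acute phase genes 14 and 13 rose (14 and 15 adjusted over the list alone), and of 10 A2 genes 7 and 5. Of 13 pan-reactive genes 12 rose in each sex, with 1 lower in females. NF-kB targets had the higher median in males: 13 of 20 rose and 2 fell in females (14 and 2 adjusted over the list alone; median 0.913), and 14 rose and 0 fell in males (15 and 2; median 1.35). Camera did not call the difference between the sexes for this list (adjusted p = 0.671). Ccl2 of this list reached 1.34 ± 1.02 CPM in LPS females and 5.39 ± 2.85 CPM in LPS males, and its difference was not called (adjusted p = 0.318). Microglia-like cells made up 0.886% or less of the cells of each LPS female and 0.921% or more in each LPS male. RNA of other cells was not corrected for, and its bearing on Ccl2 in the sexes was not tested. Ribosomal protein genes rose in 57 of 78 in females (63 adjusted over the list alone) and 3 of 78 in males (1 adjusted over the list alone). Camera called 13 lists in females, of which 9 held with an estimated correlation. Those lost were the GTPases (adjusted p = 0.056 with an estimated correlation), ER stress, with 1 gene higher and 9 lower (2 and 9 adjusted over the list alone; 0.278), oxidative phosphorylation (0.669) and ribosomal proteins (0.393). It called 12 lists in males, of which 10 held; those lost were cholesterol synthesis, with 1 higher and 14 lower of 24 (adjusted p = 0.0774), and the clock, with 6 higher and 1 lower of 16 (8 and 1 adjusted over the list alone; 0.178).

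The difference between the sexes was tested itself, as the male minus the female log2 change. Mrpl41, a mitochondrial ribosomal protein gene, reached 1135 ± 124 CPM in LPS females and 312 ± 63.1 CPM in LPS males from 98.7 and 84.0 CPM in saline (difference -1.62 ± 0.18, adjusted p = 5.83e-04). Far1, which makes the fatty alcohols of ether lipids, reached 238 ± 37.2 and 88.0 ± 10.7 CPM (-1.46 ± 0.16), and Slc37a4, the glucose-6-phosphate transporter, 230 ± 31.2 and 85.6 ± 10.4 CPM (-1.42 ± 0.16). Acss3, which overlaps Ppfia2 on the other strand, reached 24.3 ± 3.59 and 7.27 ± 0.326 CPM (-2.30 ± 0.25). Prune2 also rose more in females (-1.48 ± 0.20). Alpl (1.20 ± 0.15) and Ptgs1 (1.34 ± 0.18) fell more in females, and Fzd9, a Wnt receptor gene, fell in females (-0.78 ± 0.11) and rose in males (0.36 ± 0.11; difference 1.14 ± 0.15). Lcn2 (-1.97, adjusted p = 0.775) and Gfap (-0.79, adjusted p = 0.0535) were not called.

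The test of the difference called 482 genes, 273 with a positive and 209 with a negative male minus female change. Of these, 444 changed more in females and 38 more in males, and 154 had changes of opposite sign. Of 15 ER stress genes 8 had a positive difference (10 adjusted over the list alone; adjusted p = 0.14 by camera with an estimated correlation), namely Ddit3, Pdia6, Xbp1, Creld2, Manf, Hspa5, Sdf2l1 and Calr. Calr, a calcium-binding chaperone gene, changed by -1.12 ± 0.10 in females and by -0.07 ± 0.10 in males. Camera called 12 lists for the difference, and none held with an estimated correlation: ER stress up (adjusted p = 0.14 with an estimated correlation), transporters up, with Grm3 and Slc7a10 called (0.318), A1 down, with Fbln5 and Ggta1 (0.15), and MHC class I down, with B2m (0.318). Pan-reactive genes, with Hspb1 and Osmr, GTPases, with Irgm1, and cholesterol synthesis, with 1 gene, were down at adjusted p = 0.318 with an estimated correlation, as were acute phase genes with 2 and glucocorticoid targets with Mt2 down and Per1 up. Ribosomal proteins, with none called, were also down at 0.318, type I interferon genes, with none called, at 0.397 and oxidative phosphorylation, with none, at 0.727. Adjusted over the list alone, the counts were 12 of 16 lower for MHC class I, 6 of 11 for A1, 24 of 78 for ribosomal proteins and 3 of 13 for pan-reactive genes. They were 6 lower and 1 higher of 24 for cholesterol synthesis, 4 lower and 1 higher of 15 for glucocorticoid targets, and 7 higher and 1 lower of 20 for transporters. The count was 234 with libraries thinned, 282 with a stricter cell filter, 814 with DESeq2 and 1038 without a low-count filter. It was 256 without saline female 1, 222 without saline female 2, 311 without saline male 3, 272 without LPS male 1, 996 without LPS female 2 and 271 without LPS female 3; the 8 named genes passed in each of these.

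**Figure D3:**
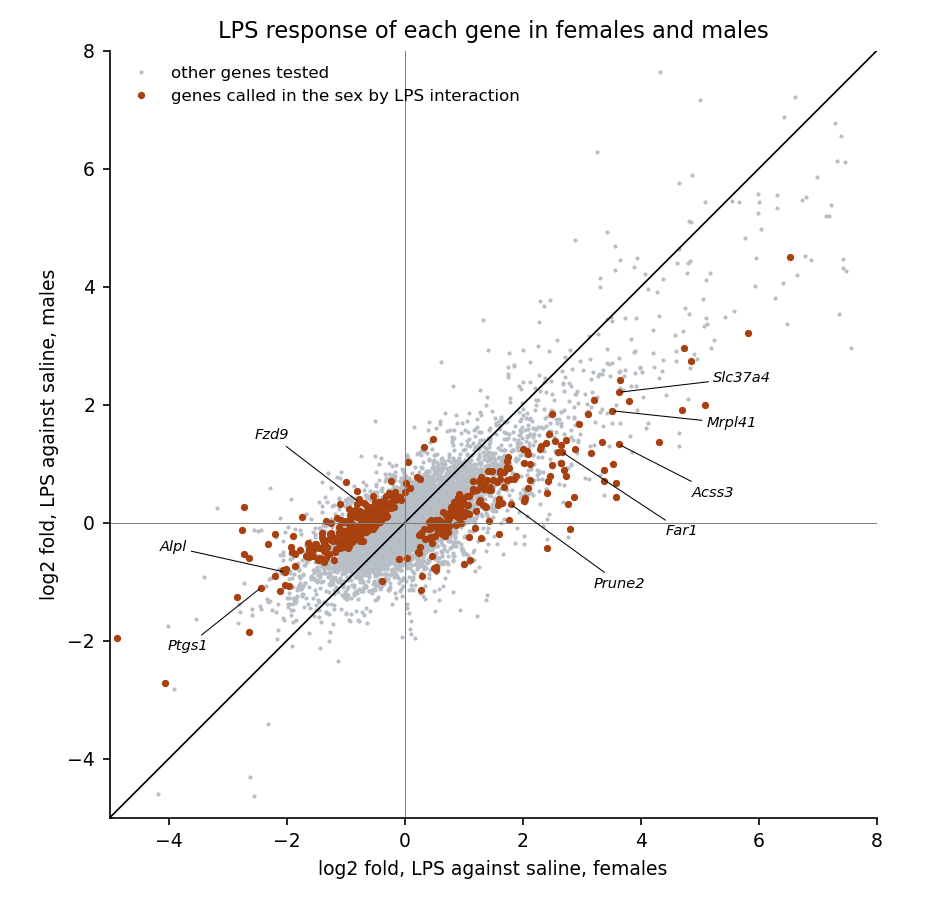
Log2 fold change after LPS in females (x axis) against males (y axis) for 14178 genes of astrocyte-like sums, with a line of equal change; 15 genes lie outside the axes. The 482 genes with a called difference are coloured and the 8 named ones labelled; most lie nearer to 0 on the male axis.

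Between saline males and females 33 genes were called, 15 higher and 18 lower in males, and 1681 of 14178 had an unadjusted p under 0.05, where chance gives 1 in 20. Recovery of changed genes was not simulated for this comparison. Xist stood at 1667 ± 48.7 CPM in females and 0.379 CPM in males (log2 male minus female -12.14 ± 0.19) and its antisense partner Tsix at -7.34 ± 0.60. The Y-linked genes Eif2s3y (12.25 ± 0.28), Kdm5d (9.13 ± 0.38) and Uty (7.01 ± 0.26) stood higher in males, Ddx3y at 79.2 ± 5.12 CPM against 0 and Gm29650 at 2.82 CPM against 0. Etnppl, an enzyme of phosphoethanolamine breakdown, stood at 63.2 ± 4.73 CPM in females and 30.3 ± 2.87 CPM in males (-1.07 ± 0.12, adjusted p = 2.53e-04). Of the lists, glucocorticoid targets were lower in males by camera, with Per1 called (-0.84 ± 0.12) and 5 of 15 lower adjusted over the list alone (adjusted p = 0.123 with an estimated correlation), as was ER stress, with 0 called and 8 of 15 adjusted over the list alone (0.141). Oxidative phosphorylation was lower with 1 gene, Atp5g3, called higher, and cholesterol synthesis was higher with 0 called and 2 adjusted over the list alone (0.957 each). The other 14 lists were not called. The 33 calls compare with 145 by DESeq2, 337 without a low-count filter and 16 with libraries thinned. Without the low-count filter 62.0% of the calls were higher in males, against 45.5%. The count was 13 without saline female 1, 12 without saline female 2, 17 without saline male 1, 70 without saline male 2 and 14 without saline male 3.

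After LPS, 1709 genes stood lower and 1416 higher in males than in females. As above, the cells of the sexes lay mostly in different clusters. Fkbp5 stood at 55.9 ± 11.1 CPM in LPS females and 14.1 ± 0.740 CPM in LPS males (male minus female -1.98 ± 0.13), Map3k6 at 36.9 ± 6.52 and 5.09 ± 1.66 CPM (-2.86 ± 0.19), and Mrpl41 differed by -1.86 ± 0.13. Xist (-12.62 ± 0.19), Eif2s3y (12.52 ± 0.27), Ddx3y (11.34 ± 0.22), Uty (8.22 ± 0.26) and Kdm5d (10.22 ± 0.39) again followed the labels. Glucocorticoid targets were lower in males, 10 of 15, and were the only list of 13 called by camera whose call held with an estimated correlation (adjusted p = 0.0306). MHC class I was lower in 15 of 16 (16 adjusted over the list alone; adjusted p = 0.27 with an estimated correlation), the GTPases in 12 of 14 (0.27), and A1 genes in 10 of 11 (0.0587). Type I interferon genes were lower in 13 of 28 (18 adjusted over the list alone), with Ifi27l2a higher (0.27), and acute phase genes in 8 of 17 with 1 higher (11 and 1; 0.27). Pan-reactive genes were lower in 5 of 13 with 2 higher (10 and 2; 0.303) and A2 genes in 5 of 10 with 1 higher (5 and 2; 0.27). Ribosomal proteins were lower in 41 of 78 (51; 0.324), oxidative phosphorylation in 24 of 86 with 2 higher (28 and 2; 0.481) and immediate early genes in 5 of 17 (0.398). ER stress genes were higher in 7 of 15 with Chac1 lower (9 and 1 adjusted over the list alone; 0.324), and transporters in 7 of 20 with 1 lower (0.324). Camera did not call NF-kB targets, with 3 higher and 4 lower of 20 (5 and 6 adjusted over the list alone; adjusted p = 0.495), or complement, with 4 lower of 9 (0.0958). Nor did it call matrix and synapse regulators (0.112), cholesterol synthesis (0.168) or the clock (0.503). In all 3125 genes were called, and 1612 with libraries thinned. It was 1686 without LPS female 1 and 1782 without LPS male 3.

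Cells of other classes were few, since the sort selects for the astrocyte reporter, and their shares describe what passed the sort. Microglia-like cells made up 0.312% ± 0.224 of saline and 0.947% ± 0.305 of LPS cells (n = 6 each; two-sided exact permutation test over 924 regroupings, p = 0.00649, adjusted p = 0.0455). Neuron-like cells made up 3.19% ± 0.975 and 2.46% ± 0.757 (exact permutation p = 0.175), and endothelial-like cells 1.06% ± 0.313 and 0.998% ± 0.347. Mural cell-like cells made up 0.494% ± 0.234 and 0.450% ± 0.171, oligodendrocyte-like 0.416% ± 0.206 and 0.390% ± 0.252, and oligodendrocyte precursor-like 0.369% ± 0.130 and 0.289% ± 0.246. Astrocyte-like, microglia-like and precursor-like shares, among others, also stood apart by sex within each treatment, which the permutation test did not take into account. Astrocyte-like cells made up 94.9% to 96.8% in females and 91.6% to 94.0% in males. Precursor-like cells made up 0.21% to 0.29% in saline females and 0.0247% to 0.109% in LPS females. In saline males they made up 0.440% to 0.544%, and in LPS males 0.441% to 0.544%. Of the 7 classes, astrocyte-like cells at 94.2% ± 1.77 and 94.5% ± 1.93 among them, the microglia-like share alone passed the adjustment. That call was lost with the stricter cell filter (adjusted p = 0.0758). It was also lost without 1 animal: saline female 1, 2 or 3 or saline male 2 (adjusted p = 0.0606 each), and LPS male 1, 2 or 3 or LPS female 2 or 3 (0.0758 each), and over all alternatives ranged from 0.0152 to 0.0758.

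In endothelial-like cells (763 cells, 26 to 148 per animal) Cxcl1, a neutrophil-attracting chemokine gene, rose from 7.53 to 314 CPM after LPS (5.06 ± 0.57, n = 6 per treatment). Lcn2, with 2 UMIs in saline, stood 1860-fold higher after LPS (95% counting interval 515 to 15400), Lrg1, with 2, 122-fold (33.5 to 1010) and Serpina3n, with 2, 60.1-fold (16.5 to 498). Ackr1, a decoy receptor for chemokines that overlaps Cadm3, had 1 UMI in saline and stood 1170-fold higher (209 to 46100), and Ch25h, cholesterol 25-hydroxylase, had 1 and stood 204-fold higher (36.4 to 8060). Tnfsf8, a ligand of the TNF family, and H2-Q7, of uncertain counts, had 0 UMIs in saline and were at least 32.4-fold and 24.9-fold higher. Cxcl12, a chemokine made by resting vessels, fell from 2887 ± 618 to 292 ± 126 CPM (-3.34 ± 0.23), Ltbp4, which binds latent TGF-beta, from 572 to 50.4 CPM (-3.44 ± 0.27), Gkn3 from 253 to 14.6 CPM (-3.87 ± 0.49), and Plekhh2 changed by -3.40. Of 4402 genes tested 578 were higher and 580 lower, against 950 and 455 without a low-count filter. Free RNA of astrocyte-like cells can enter these droplets, and astrocyte markers stood at 0.172 of their astrocyte-like level in saline and 0.154 after LPS. Of the 578 higher genes, 534 stood above the level in astrocyte-like cells, with a median ratio of 3.04 (quartiles 1.81 to 5.86), and Serpina3n stood at 0.282 of it. Tested on this class after the astrocyte results were seen, NF-kB genes rose in 9 of 9 (adjusted p = 0.00301 with an estimated correlation), MHC class I in 14 of 15 (0.0159), acute phase genes in 6 of 8 (0.0159) and pan-reactive genes in 6 of 8 with 1 lower (0.00301).

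In neuron-like cells (2004 cells, 91 to 318 per animal) Npas4, an activity-induced transcription factor gene, fell after LPS from 98.7 ± 25.5 to 18.6 ± 11.5 CPM (-2.25 ± 0.20). Fosb fell from 35.8 to 8.61 CPM (-1.79 ± 0.32). Genes of the dissociation and immediate early list, which also respond to handling of the cells, were lower in 6 and higher in 0 of 12 (adjusted p = 0.0245 with an estimated correlation, a list test chosen after the astrocyte results were seen). Outside this list, the dendritic noncoding RNA Bc1 changed by -2.14 and AC160336.1 by -1.99. The genes with the largest rises were those of the astrocyte response: Gfap from 34.7 to 235 CPM (2.73 ± 0.19), Serpina3n from 2.47 to 114 CPM (5.12 ± 0.40), Etnppl (3.03), Ifitm3 (3.45), Sult1a1 (2.74) and Lgals3bp (2.58). Lcn2, with 1 UMI in saline, stood 503-fold higher (95% counting interval 90 to 19900) and Serping1, with 2, 51.9-fold (14.1 to 433). All 8 stood at 0.176 to 0.257 of their level in astrocyte-like cells, beside astrocyte markers at 0.135 in saline and 0.194 after LPS. Of 9389 genes 496 were called higher and 485 lower; 159 of the 496 stood above the astrocyte-like level (median ratio 0.5, quartiles 0.253 to 1.36), and the lower genes had a median ratio of 6.92. Microglia-, mural cell-, oligodendrocyte- and precursor-like cells reached 20 cells in at most 2 saline animals, under the minimum of 3 per treatment set for a test, and were not tested.

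**Figure D4:**
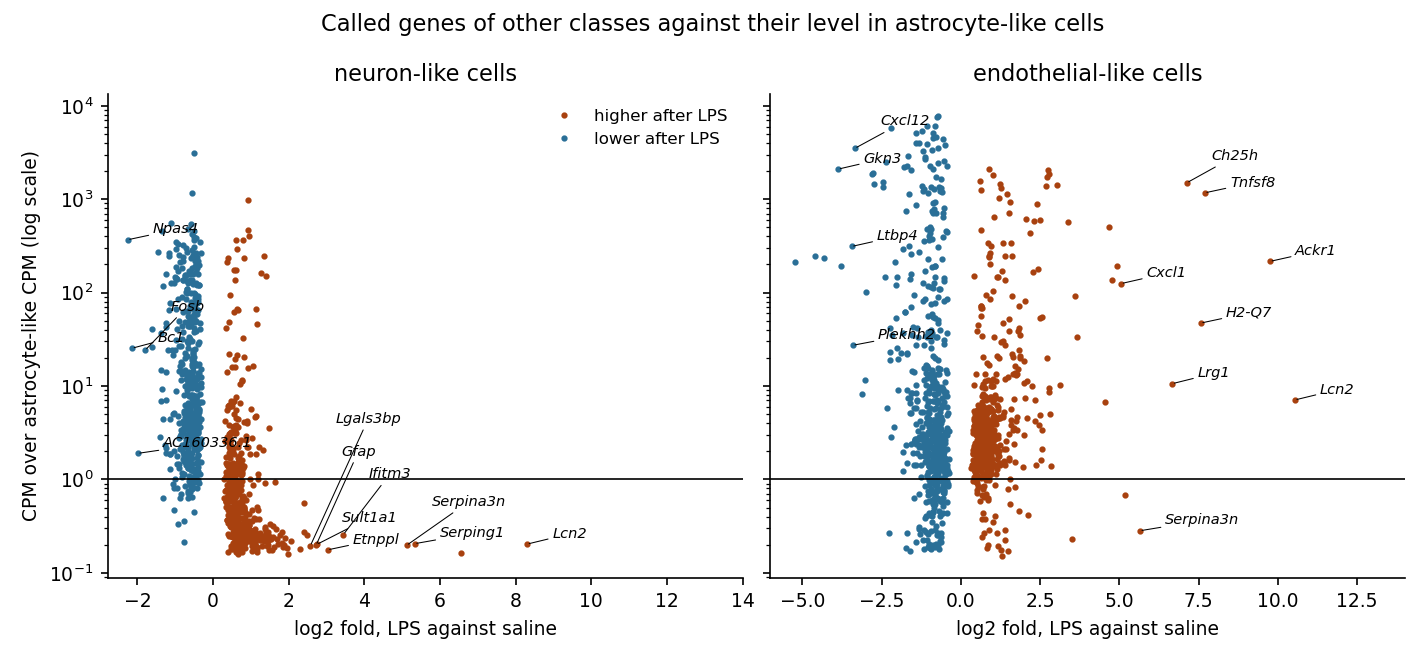
Ratio of CPM in the class to CPM in astrocyte-like cells of the treatment in which the gene was higher (y axis, log scale, line at 1) against the log2 fold change after LPS (x axis), 1 point per called gene, for neuron-like and endothelial-like sums. Of the genes called higher, 159 of 496 lie above the line in neuron-like cells and 534 of 578 in endothelial-like cells; folds of genes with 3 or fewer saline UMIs are fitted values that depend on the prior count.

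Interferon-list transcripts spread over many astrocyte-like cells after LPS. With each cell thinned to 1500 UMIs, 1.83% ± 0.232 of saline and 33% ± 12.3 of LPS astrocyte-like cells held at least 3 UMIs of the 44 genes of the type I interferon and GTPase lists (n = 6 each; two-sided exact permutation p = 0.002165, the smallest that 924 regroupings allow). LPS females stood at 43.4% ± 5.91 and LPS males at 22.6% ± 4.55 (n = 3 each; exact permutation p = 0.1, the smallest that 20 regroupings allow). Without thinning the shares were 13.7% ± 1.98 and 61.8% ± 12; shallower cells left out made up 4.69% to 15.8% of an animal's cells. Neuron-like cells, which share the free RNA of these droplets, stood at 0.462% ± 0.517 in saline and 3.90% ± 2.04 after LPS at the same depth, endothelial-like cells at 75.4% ± 11.6 and 96.0% ± 3.34, and microglia-like cells at 61.3% ± 6.82 after LPS; in saline these were 1 to 25 cells per animal, at 0% to 20%. Many cells lay near the limit of 3: after LPS 19.9% of cells had 2 UMIs, 12.8% had 3 and 7.78% had 4, and in saline 6.09%, 1.29% and 0.259%.

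**Figure D5:**
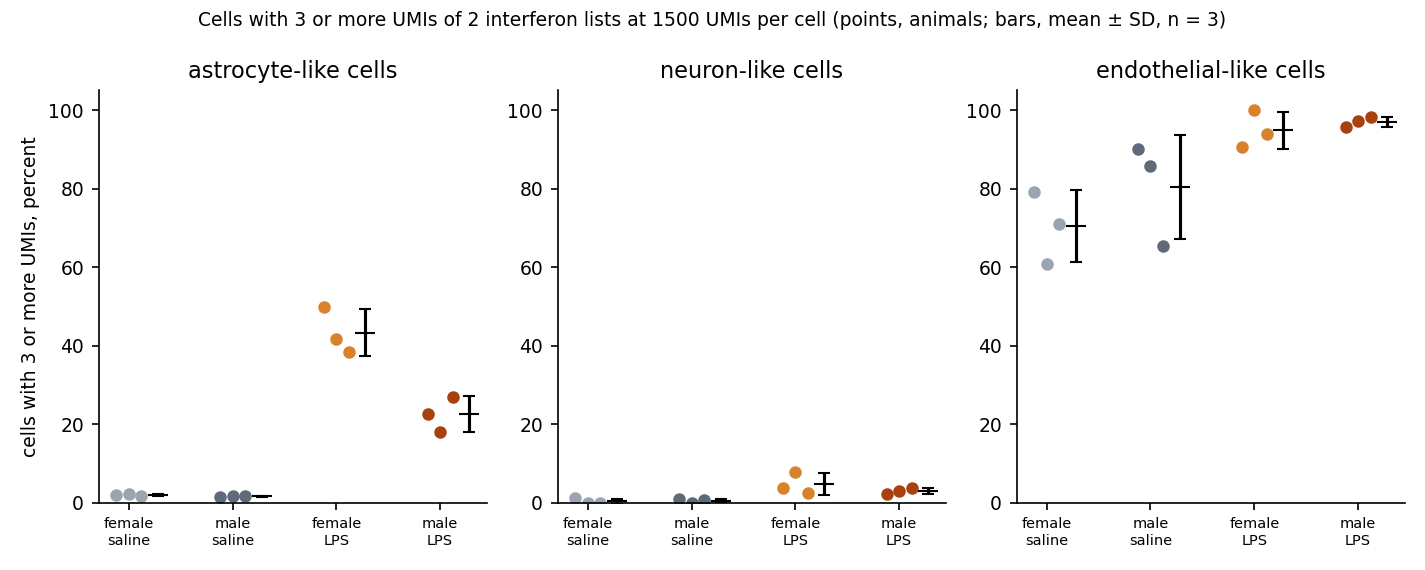
Percent of cells with at least 3 UMIs of the interferon lists after thinning to 1500 UMIs, 1 point per animal and group means with SD (n = 3), for astrocyte-, neuron- and endothelial-like cells. Astrocyte-like cells average 1.83% in saline and 33% after LPS, and neuron-like cells 0.462% and 3.90%.

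The last comparison asks whether subclusters of astrocyte-like cells, built from variable genes of saline cells less those called with an absolute log2 fold change of at least 0.5, responded differently from the remaining astrocyte-like cells of the same animal. Subcluster 5, led by Myoc, Fxyd6, Thbs4 and Gfap and holding 4.95% ± 1.67 of saline and 4.12% ± 1.35 of LPS astrocyte-like cells (n = 6 each), had the most called genes. It shares the leading genes Fxyd6, Thbs4, 6330403K07Rik, Igfbp5, Ass1 and Slc38a1 with cluster 8, whose class is in doubt. Its Gfap was high already in saline, at 1744 ± 126 CPM, and reached 4131 ± 324 CPM, while the other cells went from 153.8 to 1070 CPM (difference of log2 changes -1.52 ± 0.11). C4b, a complement gene, rose from 204.4 ± 17.3 to 559 ± 83.9 CPM in subcluster 5 and from 36.95 to 313.7 CPM outside (-1.63 ± 0.11). Prdx4 (-0.89 ± 0.09) and Ntrk2 (-0.61 ± 0.07) also had lower log2 changes there. In CPM, Gfap and C4b rose by more in subcluster 5 than outside. Larger and smaller rises in subclusters are compared on the log2 scale. Subcluster 6, led by Nkx6-2, Igsf1 and Agt, was tested in 4 saline and 6 LPS animals. There the rises of Sparc (-1.10 ± 0.10), Etnppl (-1.46 ± 0.15) and Agt (-0.68 ± 0.10) were smaller than outside and that of Meg3 was larger (1.78 ± 0.20). Meg3 is among the markers used for the neuron class, and RNA of other cells was not corrected for. Subcluster 3, led by Igfbp2, Eogt and Chrdl1, had larger rises of C4b (0.84 ± 0.10), Gfap (0.75 ± 0.09) and Unc119 (0.93 ± 0.10) and a smaller one of Nupr1 (-0.67 ± 0.07).

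Subclusters 1 and 2, the largest, differed in 54 and 44 genes. Unc119 rose more in subcluster 1 (0.98 ± 0.12), as did Gfap (0.52 ± 0.08), and Rbm3 (-0.91 ± 0.12) and Gap43 (-1.56 ± 0.25) rose less. In subcluster 2 Unc119 (-0.93 ± 0.10), Lcat (-0.48 ± 0.07) and Srsf3 (-0.47 ± 0.07) had lower and Nr4a1 (1.33 ± 0.21) a higher change than outside. Subclusters 7 and 9 were tested in 5 saline and 6 LPS animals each. Subcluster 9 differed in 6 genes, among them Csrp1 (0.83 ± 0.20), Celf1 (1.36 ± 0.35) and Gm47283 (0.98 ± 0.23), a pseudoautosomal gene of uncertain counts. Each of these 3 calls was lost with at least 50 cells per animal (adjusted p = 0.117 for Csrp1, 0.122 for Celf1 and 0.158 for Gm47283), and that of Celf1 with median-of-ratios size factors (0.0639). Each was also lost without 1 animal. That of Gm47283 was lost without saline female 1 or 2 or LPS male 1 (adjusted p = 0.0777 to 0.184). That of Csrp1 was lost without saline female 1 or 2, saline male 3, LPS female 1 or LPS male 1 or 3 (0.0524 to 0.139), and that of Celf1 without saline female 1, 2 or 3, saline male 1, LPS male 2 or LPS female 3 (0.0593 to 0.316). In subclusters 4, 7 and 8 the smallest adjusted p belonged partly to markers of red blood cells and choroid plexus. Hba-a1, Hba-a2 and Hbb-bt in subcluster 4, Hbb-bs and Ttr in 7, and Ttr, Hbb-bt and Enpp2 in 8 had SDs near or above their means, as in Hbb-bt of subcluster 4 at 1454 ± 3560 CPM in saline; the globin genes are also close copies. The other named genes there were Gfap in 4 (0.62 ± 0.10), Chil1 (-1.28 ± 0.19) and Adam11 (-2.65 ± 0.42) in 7, and Clk1 in 8 (2.53 ± 0.42). In all, 543 of 112542 pairs of gene and subcluster were called by edgeR's test, 210 of them in subcluster 5. Of the 543, 204 had a higher and 339 a lower log2 change inside, so the 339 can include genes that fell further there. Subcluster 4 held 54.9% of the astrocyte-like cells of LPS female 1 and 4.77% to 16.2% in the other LPS animals. The count was 945 at Leiden resolution 1 and 345 without saline male 1. Without saline male 3 the globin changes in subcluster 4 turned to 5.81 for Hba-a2, 4.55 for Hbb-bt and 3.35 for Hba-a1, and without saline male 1 Ttr turned to -0.13 in subcluster 7 and 3.43 in 8 and Enpp2 to 1.90 in 8. Adam11 lost its call without saline male 1 (adjusted p from 3.05e-10 to 0.552 over the alternatives), Hbb-bs in 7 without LPS male 3 (5.6e-10 to 0.549), Hbb-bt in 8 without saline female 3 (2.94e-44 to 1), and Ttr in 7 with at least 50 cells per animal (6.96e-10 to 0.991).

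The interferon-list share within LPS animals ranged from 24.1% ± 12.3 in subcluster 9 (5 animals) to 39.8% ± 6.64 in subcluster 5 (6 animals). Subcluster 6 stood below the remaining cells of its animals by 8.88 points (SD 4.57, lower in 6 of 6 animals), subcluster 1 stood lower in 6 of 6 animals, and subcluster 4 higher in 6 of 6. None of the 9 subclusters passed the adjustment in the two-sided exact sign-flip permutation test (smallest adjusted p = 0.0938), and 3 had an unadjusted p of 0.0312, the smallest that 6 animals allow. With that smallest p, the adjustment can be passed only where most of the 9 subclusters reach it together. The test therefore could not call 1 subcluster alone.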

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

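The tests of sequencing depth and of cells without a response were chosen after the results they bear on were seen; the other tests in this part were set beforehand. The response to LPS differed between the sexes, by a test of the difference itself, in 482 genes. That count was 256 without saline female 1, 222 without saline female 2, 311 without saline male 3, 272 without LPS male 1, 996 without LPS female 2 and 271 without LPS female 3. Among the 8 named by rule the male minus female change on the log2 scale was -1.46 for Far1, -2.30 for Acss3, -1.42 for Slc37a4, -1.62 for Mrpl41, -1.48 for Prune2, 1.20 for Alpl, 1.14 for Fzd9 and 1.34 for Ptgs1. The class shares and the interferon-list share were tested for a sample far from the others, in 16 groups of 6 animals of a treatment. Of such samples 0 were found, where chance gives about 1 in 20. Shares of clusters and subclusters were not tested in this way. Cluster 10 held 16.8% of the astrocyte-like cells of LPS female 1 and 0.327% to 2.64% in the other LPS animals.

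The response was larger in females, with 6146 genes called against 2628 in males. The tables argue against a difference in depth between libraries as the whole cause, since with every library thinned to the smallest total the female count was 2.65 times the male count. Clusters 3, 5 and 6, which hold most saline cells, made up at most 4.03% of the astrocyte-like cells of a male LPS library. Few astrocyte-like cells of the male LPS libraries thus lay in those clusters. Other clusters were held by both treatments, as cluster 8 at 4.39% ± 1.40 in saline and 4.39% ± 1.24 after LPS. The clusters were also built without leaving out genes that LPS changed, and free RNA was not corrected. The share therefore does not exclude a mixture of cells with and without a response in the male LPS libraries. A measure tried first, the male rise in CPM over the female rise in 56 genes (median 0.427, quartiles 0.316 to 0.595), did not exclude such a mixture. Sex itself, the timing or strength of the response in all cells, and a day or batch shared by the animals of 1 sex, which the labels do not give, stay open and were not tested. The median mitochondrial percent of astrocyte-like cells was 3.76 to 3.92 in LPS females and 4.23 to 4.59 in LPS males. It was 4.46 to 4.87 in saline animals, and the bearing of this difference on the counts was not tested.

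Genes called higher in neuron-like cells included those of the astrocyte response. RNA of astrocyte-like cells in the droplets was weighed by the ratio of their CPM to that in astrocyte-like cells, whose median was 0.5 (quartiles 0.253 to 1.36), at the limit set beforehand. Such RNA and a change in the neuron-like cells themselves therefore cannot be told apart for these genes as a set, and the width of the ratios keeps this open; the 8 named genes stood at 0.176 to 0.257, and astrocyte markers at 0.194 after LPS.

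For genes called higher in endothelial-like cells, the same ratio had a median of 3.04 (quartiles 1.81 to 5.86), which argues against RNA of astrocyte-like cells in the droplets as the source of most of them. Serpina3n, at 0.282 of its astrocyte-like level, is an exception and stays open. A change in which vessel cells passed the sort was not tested.

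Of 100 splits of the animals by sex within treatment, 4 gave as many genes with a different response as the real one, itself included (482, highest other 1790). The 3 others kept the LPS animals divided by sex (0 or 6 of them exchanged) and exchanged 4 or 6 saline animals. The split with 897 genes exchanged all 6 LPS and 4 saline animals, which equals exchanging only the remaining saline animals. The split with 1790 exchanged the 6 saline animals alone. It thus tested the sum of the sex differences in LPS and in saline, not their difference. Its count points to sex differences in the samples, but not to those of the LPS animals alone. The splits also break up the division of the LPS animals by sex, where 3125 genes differed. Their share therefore does not exclude chance for the difference in response itself, which stays open.

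Other splits of the animals between LPS and saline within each sex excluded chance for the astrocyte-like count (1 of 100 splits gave as many; 6638 genes, highest other 2979) and for neuron-like cells (1 of 100; 981 and 7). They also excluded it for endothelial-like cells (1 of 100, with 1158 and 60). For the subclusters 1 of 22 splits gave as many (543, highest other 57, median of the others 26). That share is the smallest that 22 splits allow and lies just under 0.05, so it argues against chance less strongly. Chance cannot be excluded for the number of gene lists called by camera at its preset correlation, since 38 of 100 splits gave as many (13, highest other 17). Comparisons of 3 animals with 3 have 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, gave as many genes as it did for LPS against saline in females (6146, highest other 0) and in males (2628 and 0), and for male against female in saline (33 and 2) and in LPS (3125 and 5).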

How the results depend on the processing

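The runs without cluster 8 and without clusters 10, 11 and 15 were chosen after seeing the data; the other alternatives were fixed before the data were examined. Counts and shares that answer a comparison stayed within the limits set (1.5 times for a count) in 83 of 94 runs of other settings and in 133 of 156 runs without 1 animal. Of 3480 values of 178 named results (a gene counted once per comparison) under the alternatives, 3424 had the same direction and side of the threshold. Those that moved were the sex by LPS interaction (482; DESeq2 814, no low-count filter 1038, stricter cell filter 282, thinned libraries 234) and male against female in saline (33; DESeq2 145, no low-count filter 337, thinned 16). Others were male against female in LPS (3125; thinned 1612), LPS against saline in males (2628; thinned 1560), the subclusters (543; resolution 1.0 945) and the number of class shares called (1; stricter cell filter 0). Fewer counts per library account for the thinned values by construction, and for the others the cause was not tested. The call of the oxidative phosphorylation list was lost with fry, with an estimated correlation and without 6 of the animals.

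Without 1 animal the counts ranged from 5937 to 6803 for LPS against saline, 5020 to 6644 in females, and 1776 to 2851 in males. They ranged from 222 (without saline female 2) to 996 (without LPS female 2) for the interaction, 12 (without saline female 2) to 70 (without saline male 2) for male against female in saline, and 1686 (without LPS female 1) to 3697 (without saline male 1) in LPS. They ranged from 12 to 14 for gene lists, 711 to 925 in neuron-like cells, 1014 to 1171 in endothelial-like cells, and 1790 to 2016 in both together. The ranges were 0 to 1 for class shares, 345 (without saline male 1) to 638 for subclusters, and 27.74 to 34.13 percentage points for cells with interferon-list transcripts. The interaction also moved over 1.5 times without saline female 1 (256), saline male 3 (311), LPS male 1 (272) or LPS female 3 (271). Male against female moved in saline without saline female 1 (13), saline male 1 (17) or saline male 3 (14), and in LPS without LPS male 3 (1782). The class share was lost without saline female 1, 2 or 3, saline male 2, LPS male 1, 2 or 3, or LPS female 2 or 3 (0 each).

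Signs turned as follows, with the range without 1 animal, and the cause was not tested. For LPS against saline, Eif2s3y, which was not called, went to 0.82 with thinned libraries and 0.68 without saline female 2 (from -1.20), Xist, not called, to 0.0588 without saline male 3 (from -0.37), and the sign of the transporter list, not called, to -1 without LPS female 2. Differences of class shares that were not called also turned, in percentage points. Astrocyte-like cells went to -0.0667 with doublets retained, -0.118 without saline male 1 and -0.152 without LPS female 1 (up to 0.885). Endothelial-like cells went to 0.0668 with doublets retained, 0.00153 without saline male 2, 0.0145 without saline male 3 and 0.00619 without LPS female 1 (from -0.184). Oligodendrocyte-like cells went to 0.00503 without saline female 1, 0.0405 without saline male 2, 0.00864, 0.0188 and 0.00291 without LPS female 1, 2 and 3 (from -0.101), and mural cell-like cells to 0.00298 without saline male 3 (from -0.108). The interferon-list share, over the other cells, went to 2.66 in subcluster 9 at 1 UMI or more, and to 0.0802 in subcluster 2 and -0.676 in subcluster 7 at 10 or more. In subcluster 4 Hba-a2 (from -9.80) went to 5.81, Hbb-bt (from -9.03) to 4.55 and Hba-a1 (from -7.33) to 3.35 both with at least 50 cells per animal and without saline male 3. Without saline male 1, Ttr went to -0.13 in subcluster 7 (up to 4.05) and 3.43 in 8 (from -5.44), and Enpp2 to 1.90 in 8 (from -2.50).

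The values did not show that replicate numbers pair the animals, and they cannot exclude it. Of 18 pairs with the same number in different groups, 3 had deviations correlated above 0.1 (median 0.01, from -0.102 to 0.181). These 3 pairs were all of animals numbered 3 (0.133, 0.125 and 0.181), and 2 of 12 animals correlated best with their own number. With the replicate block the counts were 6550 for LPS against saline, 6056 in females, 2501 in males, and 452 for the interaction. They were 48 and 2952 for male against female in saline and LPS, 1090 in neuron-like cells, 1156 in endothelial-like cells, 2246 in both and 12 for lists, where oxidative phosphorylation was not called. The limit of at least 50 cells could not be run for endothelial-like cells, since too few animals reach it.

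On simulated endothelial-like sums (4128 genes) 24% of genes changed by 0.5 and 77% of those changed by 1 on the log2 scale were recovered.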

Other observations

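The list tests in this part were chosen after the astrocyte results were seen. In endothelial-like cells 48 of 77 ribosomal protein genes stood higher after LPS and 0 lower (adjusted p = 0.297 by camera with an estimated correlation), as did 27 of 76 oxidative phosphorylation genes with 1 lower (0.128). ER stress genes were higher in 7 of 13 and lower in 0 there (0.104), and higher in 3 and lower in 8 of 15 in astrocyte-like cells; the difference between the classes was not tested. Interferon genes, whose transcripts endothelial-like cells held in saline as well, were higher in 8 of 22 for the type I response (0.316) and in 5 of 10 with 1 lower for the GTPases (0.2). A1 genes were higher in 5 of 6 (0.0972), glucocorticoid targets in 5 of 8 with 1 lower (0.128), and matrix and synapse regulators lower in 5 of 8 (0.128). At the preset correlation camera called each of these lists, with adjusted p from 4.58e-13 for ribosomal proteins to 0.0158 for the GTPases. With an estimated correlation none of them was called. Camera called neither way dissociation and immediate early genes (5 higher and 3 lower of 15, 0.674 with an estimated correlation), transporters (1 and 2 of 14, 0.702) and cholesterol synthesis (1 and 0 of 10, 0.876).

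In neuron-like cells, where astrocyte RNA in the droplets stays open, pan-reactive genes were higher in 5 of 5 (adjusted p = 0.000483 with an estimated correlation), glucocorticoid targets in 7 of 11 (0.000951), the type I interferon response in 4 of 6 (0.00192), and MHC class I in 5 of 8 (0.00596). Higher too were acute phase genes in 3 of 7 (0.00641), astrocyte transporters in 8 of 19 (0.0458) and the clock in 3 of 15 (0.0458). ER stress genes were lower in 3 of 14 (0.373), ribosomal proteins higher in 12 of 77 (0.373), and oxidative phosphorylation in 8 of 78 with 1 lower (0.373). Matrix and synapse regulators were higher in 2 of 12 (0.18), and cholesterol synthesis lower in 3 of 22 with 1 higher (0.135).

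The first principal component of the astrocyte-like sums held 58.1% of the variance and placed the 6 saline animals at -40.8 to -32.9, the LPS males at 15.9 to 23.2 and the LPS females at 47.1 to 61.3. The second held 12.9% and placed the females at 10.9 to 25.5 and the males at -2.28 or below, over both treatments. LPS male 2 had the lowest level among LPS animals of Lcn2 (126 CPM, against 592 and 853 in the other LPS males), Serpina3n (198, against 565 and 605) and Gfap (841, against 1279 and 1108). Its astrocyte-like cells lay in clusters 3, 5 and 6 at 4.03%, against 1.47% and 1.31%.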
